A study of Mus musculus with 12 samples.

How the data were processed

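Gene expression was measured on 12 Illumina bead arrays hybridised with biotin-labelled copies of total RNA from 6 mouse cell lines derived from tumours. The labels give 3 lines with wild-type STAT3 and 3 lines with constitutively active STAT3, and 2 replicate arrays for each line. Nothing in the labels says that the replicate arrays of a line came from separate cultures, so p-values that rest on them measure only the spread between arrays, which may be technical. Per the labels' protocols the cells were grown in RPMI medium with foetal calf serum, RNA was extracted with Trizol and purified on a column, and it was amplified and labelled with a commercial kit. The tissue of the tumours is not named in the labels.

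The deposited raw table holds, for each array and 46632 probes, a summarised bead intensity on a linear scale and a detection value given as a fraction from 0 to 1, per the file headers. The detection fraction increased with the intensity (Spearman's rho across probes between 0.997 and 0.998 on each array), so 1 minus the deposited fraction was used as the detection p-value. The deposited series matrix holds processed values of the same arrays on a log2 scale. The submitters' processing notes name BeadStudio 3.1.7 and lumi. The background correction and normalization behind the deposited log2 values are not given in the sources used here. Their column medians lay between 7.01 and 7.02, they kept the order of the raw signals on each array (Spearman's rho of 1), and their Pearson correlation with the log2 raw signals lay between 0.988 and 0.998, so the scale is known and the values were not centred per gene. They served as an alternative.

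The main values were computed from the raw signals with limma 3.58.1 in R 4.3.3: normal-exponential background correction by detection p-values with an offset of 16, quantile normalization and log2 (function neqc). A probe was kept if its detection p was under 0.01 on both arrays of at least 3 of the 6 lines, which left 11650 probes. Gene symbols came from the platform annotation, in which 29976 of the 46632 probes had exactly 1 symbol, 10 had several and 16646 were unnamed here. Through Entrez identifiers 29921 of the 29986 listed probes were found in a RefSeq gene table of the GRCm38.p6 mouse assembly, and no symbol changed. The build used for the array is not given in the sources used here, so no coordinates are printed and that table served only for names and gene order. For each gene the kept probe with the highest mean over the 12 arrays was tested, which gave 7306 genes, of which 1709 had more than 1 kept probe. The offset holds dim probes near the lower end of the scale, so folds of genes close to background are understated.

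The genotype varies between lines, so the line was the replicate. The 2 arrays of a line were averaged, and 3 lines were compared with 3 lines by the moderated test of limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment at 0.05. An exact permutation test of 3 lines against 3 cannot go below p = 0.1, so no permutation p is given for single genes. Differences among the 3 lines of a genotype were tested with a moderated F test in 1 model of the 6 line means, with the arrays within a line as the residual. Log2 fold changes are constitutively active minus wild-type. Values are line means of log2 signal with the SD over lines (n = 3 lines per genotype), or over the 2 arrays of a line. Where no probe of a gene was detected on any array of a genotype or a line, the fold is a lower bound: the mean of the bright side against the mean of the higher of the dim probe's own signal and the lowest signal among detected probes on each array.

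Before the data were examined, 23 gene lists were fixed: STAT3 target genes, acute-phase proteins, cytokines and chemokines, focal adhesion and tensins, epithelial junctions and keratins, mesenchymal and fibroblast markers, basal and myoepithelial markers, luminal mammary and milk genes, leukocyte markers, endothelial markers, adipocyte markers, interferon-stimulated genes, MHC class I antigen presentation, proliferation, glycolysis, hypoxia response, oxidative phosphorylation, proteases and matrix remodelling, ERBB receptors with their ligands and feedback genes, apoptosis regulators, p53 target genes, heat shock and ER stress, and Notch and Wnt pathway. They hold 528 symbols, of which 526 were found in the gene table. Tns4 was put in the focal adhesion list because the study is known to concern it, so its place there is not independent evidence. Lists were tested with camera at its preset correlation of 0.01, two-sided, with estimated correlation and fry as alternatives. For models with a random block the preranked form of camera was applied to the moderated statistics.

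The rule for named genes was also fixed before the data were examined. It names Stat3, the 12 genes with the largest fold change in each direction among those past the threshold, filled up to 12 with genes whose 3 lines of one genotype all lay above the 3 of the other in order of the moderated p and described as not passing, the members of each list past the threshold or otherwise the up to 4 with the smallest p, and the 5 genes with the widest range of line means in each genotype. Of the named list members the text gives a part, and it gives other list members for single lines; both were chosen after their values were seen.

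Alternatives were the deposited log2 values, no background correction (raw signals under 1 set to 1), median scaling in place of quantile normalization, no detection filter, detection on all 12 arrays, every probe tested separately, the line as a random block (duplicateCorrelation), 12 independent arrays, replicate number or cell line number as a fixed block, a trended and robust prior, adjusted p under 0.1, a log2 fold threshold of 1, and leaving out each array or line. Slides could not be used as a block because the sources used here do not give them. The replicate numbers did not pair arrays across lines: correlations of the deviations of replicate 1 arrays from their line means ran from -0.26 to 0.31 over the pairs of lines. Nor did the cell line numbers pair lines across genotypes, with correlations of 0.21, -0.27 and -0.18.

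The scripts were tested on simulated data made from the real line means and spreads of the 7306 genes. In the genotype comparison, 35 of 50 genes changed 2-fold were recovered, 47 of 50 changed 4-fold, 49 of 50 changed 8-fold and 50 of 50 changed 16-fold, with 6 unchanged genes called, and 0 genes were called when nothing was changed. Simulated genes varied independently, with the spreads of the moderated fit, and many were changed at once, which eases the adjusted threshold. These shares may therefore overstate what the real comparison could recover. In the F test among wild-type lines, 57 of 66 genes changed 1.5-fold in 1 line and 66 of 66 changed 2-fold were recovered. A list of 20 genes shifted by 1 log2 unit gave a camera p of 7.86e-33 and an unshifted one 0.789. Members of these simulated lists varied independently, so this does not show how camera performs where members vary together. In the real interferon list, for instance, the estimated correlation was 0.84. On arrays the number of arrays and lines limits the precision.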

Results

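The data describe the transcriptomes of 6 mouse cell lines derived from tumours, 3 with wild-type STAT3 and 3 with constitutively active STAT3, each measured on 2 bead arrays. STAT3 is a transcription factor that cytokine and growth factor receptors switch on by phosphorylation. The labels call the altered form constitutively active, and whether it still needs that signal was not examined here. The question was which genes differ in expression between lines of these genotypes. Between 11002 and 12798 of 46632 probes were detected per array (23.6% to 27.4%), and 7306 genes were tested. The 2 arrays of a line correlated at 0.993 to 0.998 across genes, with a median absolute difference between 0.08 and 0.12 on the log2 scale. The upper end of the raw signals moved with the genotype before normalization: the brightest probe read 38552 to 44974 on the arrays of constitutively active lines and 30306 to 34189 on those of wild-type lines, a difference with an exact two-sided permutation p of 0.1 over lines, the smallest that 3 lines against 3 allow. Quantile normalization sets the signal distributions equal. The sources used here give no slide or hybridisation batch, so a batch that went with the genotype cannot be told apart from it.

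All 6 lines had bright signals for the epithelial keratin genes Krt8 and Krt18, whereas Krt19 of the same list was undetected in wild-type line 1 and constitutively active line 1. Krt18 line means lay between 13.44 and 13.82 on the log2 scale, and the Krt8 genotype means were 13.77 ± 0.21 in constitutively active and 13.79 ± 0.12 in wild-type lines (SD, n = 3 lines each). Markers of other cell types were mostly undetected. Of 16 leukocyte markers on the array 13 were detected on no array, as were 10 of 13 endothelial markers, 8 of 10 adipocyte markers and 16 of 26 mesenchymal and fibroblast markers. Others were detected on all 12 arrays, namely 1 leukocyte, 3 endothelial and 5 mesenchymal markers, such as Cd14 and Fn1. Their genotype means lay at 12.37 and 12.40 for Cd14 and at 10.45 and 10.58 for Fn1. The share detected on no array was not counted over all genes, and only 7306 of 17711 symbols passed the filter. These counts therefore do not show that such markers were rarer than other genes. No adipocyte gene passed the filter, so that list was not tested.

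The lines did not group by genotype. Across genes the highest correlation between lines was that of wild-type line 3 with constitutively active line 2 (0.982), and the lowest that of wild-type line 1 with constitutively active line 3 (0.921). The leading 2 principal components held 37.1% and 23.8% of the variance and set apart constitutively active line 3 and wild-type line 1. Of all the variation in the tested genes 15.3% lay between genotypes, 78.9% between lines of a genotype and 5.75% between arrays of a line. Of the variation between lines alone 16.2% lay between genotypes, where 20% would be the chance share.

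**Figure D1:**
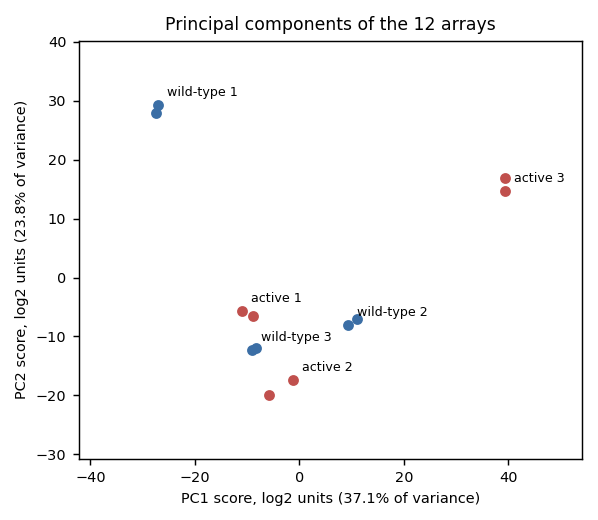
Scores of the 12 arrays on the leading 2 principal components of the 7306 tested genes, in log2 units (x axis 37.1% and y axis 23.8% of the variance), with wild-type lines in blue and constitutively active lines in red and 1 point per array. The 2 arrays of a line lie together, and the genotypes overlap, with wild-type line 3 between constitutively active lines 1 and 2 on the y axis.

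Between genotypes, no gene passed the adjusted threshold, and the transcript of Stat3 itself was not higher in the constitutively active lines. Stat3 signal was 12.17 ± 0.63 in constitutively active and 12.66 ± 0.21 in wild-type lines (SD, n = 3 lines each), a log2 fold change of -0.49 (limma adjusted p = 0.898). The difference rested largely on constitutively active line 3, at 11.50 against 12.74 and 12.27 in lines 1 and 2, and was -0.16 without that line. The other kept probe of Stat3 gave -0.75. The probes read the amount of transcript and are not known here to tell the mutant from the wild-type allele. Tns4, which encodes tensin 4, also called Cten, a focal adhesion protein, was not detected on any wild-type array and was detected on all 6 constitutively active arrays, at least 8.21-fold brighter on average. Its line means were 4.86, 5.53 and 6.09 in wild-type lines and 6.75, 8.28 and 12.45 in constitutively active lines, so that the average rested largely on constitutively active line 3, and the difference did not pass (log2 fold change 3.67, limma adjusted p = 0.854). Socs3, a feedback inhibitor that STAT3 induces, stood at 8.83 ± 0.48 against 8.04 ± 0.58 (limma adjusted p = 0.858), with line ranges that overlapped.

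With 0 genes past the limma threshold, and 0 with the line as a random block, 410 genes had an unadjusted p under 0.05, 148 higher and 262 lower in constitutively active lines, where chance gives 365.3. The lines of the genotypes did not overlap for 909 genes, 12.4% of those tested, where chance gives 10%, with 436 higher and 473 lower. Other splits of the 6 lines into 3 and 3, run after the results were seen, gave 285 to 1281 genes without overlap. Leaving out wild-type line 1 gave 188 genes at an unadjusted p under 0.05. Median scaling gave 831 higher and 52 lower and moved the median log2 fold change of all genes from 0.01 to 0.21, so directions hold only relative to the quantile-normalized distribution. The 12 such genes with the smallest p among those higher in constitutively active lines were Gdpd3, Slc4a11, Hsd17b7, 1700084E18Rik, P2ry2, AU018091, Map11, Stk19, Melk, Mcrip2, Plrg1 and Prag1. None passed, each with an adjusted p of 0.854. P2ry2, a receptor for extracellular nucleotides, averaged 10.62 ± 0.40 against 9.19 ± 0.57 (2.70-fold). Slc4a11, a membrane transporter, averaged 7.75 ± 0.23 against 6.71 ± 0.30 (2.06-fold), and Gdpd3, a phosphodiesterase of lysophospholipids, 9.17 ± 0.23 against 8.15 ± 0.27 (2.03-fold). Hsd17b7, an enzyme of cholesterol synthesis, averaged 11.44 ± 0.20 against 10.72 ± 0.12 (1.64-fold). Melk, a kinase of dividing cells, averaged 6.80 ± 0.27 against 6.13 ± 0.16 and was detected on 3 of 6 wild-type arrays. No wild-type array detected 1700084E18Rik, which was at least 1.30-fold brighter in constitutively active lines. Stk19 has 3 kept probes whose log2 fold changes ran from 0.11 to 0.38.

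The corresponding 12 genes lower in constitutively active lines were Hadhb, Rnf145, Lipa, Spc25, Ndufv2, Rab7, Smim14, Zfp317, Rpl10, Sec61g, Canx and Dpp4, again each with an adjusted p of 0.854. Hadhb, a subunit of the mitochondrial enzyme of fatty acid oxidation, averaged 8.50 ± 0.01 against 9.29 ± 0.11 (1.72-fold higher in wild-type lines), but its other kept probe gave a log2 fold change of -0.14. Lipa, the lysosomal acid lipase, averaged 7.83 ± 0.14 against 8.59 ± 0.08 (1.69-fold). Ndufv2, a subunit of respiratory complex I, averaged 9.20 ± 0.12 against 9.85 ± 0.04, and Rnf145, a ubiquitin ligase of the endoplasmic reticulum, 9.64 ± 0.04 against 10.28 ± 0.04. Sec61g and Canx, which serve protein entry and folding in the endoplasmic reticulum, averaged 10.20 ± 0.15 against 10.84 ± 0.08 and 7.80 ± 0.06 against 8.35 ± 0.10. Kept probes disagreed for Rab7, a small GTPase of late endosomes (-0.52 to -0.07), and for Zfp317, whose probes ran from -0.58 to 0.01 and whose log2 fold change was 0.00622 among probes detected on all arrays.

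**Figure D2:**
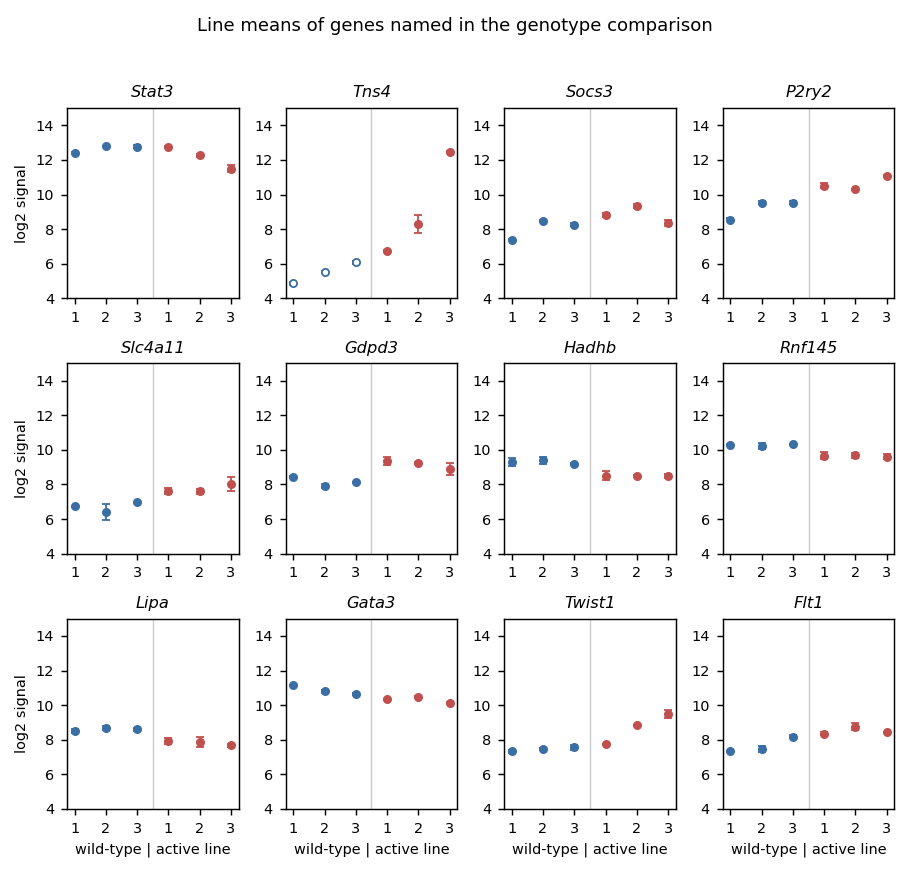
Log2 signal of 12 genes in each of the 3 wild-type lines (blue) and 3 constitutively active lines (red); points are means of 2 arrays, bars the SD of those arrays, and open points mark lines in which fewer than both arrays detected the plotted probe. Tns4 runs from 4.86 to 6.09 in wild-type and from 6.75 to 12.45 in constitutively active lines, while Hadhb, Rnf145 and Lipa lie lower in all 3 constitutively active lines by under 1 log2 unit; none passed the adjusted threshold.

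No gene list shifted between genotypes by camera, and over all lists 0 members passed over all genes tested and 1 when adjusted over the list alone. The smallest camera adjusted p was 0.380, shared by luminal mammary and milk genes, endothelial markers, oxidative phosphorylation, and heat shock and ER stress; with an estimated correlation the smallest adjusted p was 0.962, and with fry, which tests whether genes of a list move one way on balance, 0.0790. The counts of higher and lower members below were not recomputed with median scaling. Of 12 luminal and milk genes tested 9 were lower and 3 higher in constitutively active lines. Gata3, a transcription factor of luminal cells, stood at 10.31 ± 0.15 against 10.86 ± 0.27, and the secreted protein gene Wfdc18 at 12.76 ± 0.27 against 13.17 ± 0.05, while Ltf, encoding lactotransferrin, stood at 14.32 ± 0.32 against 13.36 ± 0.69. All 3 endothelial markers tested were higher. Flt1, a receptor for vascular endothelial growth factor, stood at 8.52 ± 0.21 against 7.66 ± 0.44 and was the member that passed when adjusted over the list alone (adjusted p = 0.0385), but not over all genes (0.854). Of 33 oxidative phosphorylation genes 21 were lower, but the median log2 fold change of the list was only -0.035. Its members with the smallest p were Atp5pb, at 10.70 ± 0.15 against 11.06 ± 0.06, and Cox8a, at 13.12 ± 0.06 against 13.39 ± 0.10. Of 13 heat shock and ER stress genes 9 were lower, among them Atf4 (8.81 ± 0.26 against 9.39 ± 0.21) and the chaperone gene Hsp90b1 (11.20 ± 0.28 against 11.74 ± 0.23).

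Of 21 STAT3 target genes tested 13 were higher and 8 lower in constitutively active lines, and the list did not pass (camera adjusted p = 0.759). Its other members with the smallest p were Bcl3 (7.86 ± 0.24 against 7.02 ± 1.04) and Myc (7.47 ± 0.06 against 7.24 ± 0.24). The same adjusted p of 0.759 held for epithelial junctions and keratins (7 of 18 higher), basal and myoepithelial markers (9 of 9 higher, but 2 of 9 without wild-type line 1), interferon-stimulated genes (7 of 9), MHC class I antigen presentation (5 of 11), glycolysis (4 of 14), and proteases and matrix remodelling (7 of 13). For focal adhesion and tensins 13 of 21 were higher (adjusted p = 0.822). Beside Tns4, the members with the smallest p were the adaptor gene Pxn at 8.46 ± 0.16 against 8.87 ± 0.30, Vcl at 9.70 ± 0.41 against 10.16 ± 0.22 and Tln1 at 9.31 ± 0.39 against 8.79 ± 0.22. Of the epithelial list the junction genes Dsg2 (9.29 ± 0.07 against 9.70 ± 0.27) and Cdh1 (8.54 ± 0.21 against 8.91 ± 0.20) had the smallest p, but kept probes disagreed, with log2 fold changes from -0.41 to 0.06 for Dsg2 and of -0.37 and -0.00318 for Cdh1. Those for Pxn were -0.41 and -0.08. Of 7 mesenchymal and fibroblast markers 5 were higher (0.822), and Twist1, a transcription factor of mesenchymal cells, stood at 8.69 ± 0.86 against 7.44 ± 0.12. Adjusted p-values were 0.804 for hypoxia response (4 of 11 higher) and for the ERBB list (7 of 16), 0.807 for p53 target genes (6 of 10), 0.822 for Notch and Wnt pathway (4 of 11), 0.941 for cytokines and chemokines (5 of 10), 0.962 for acute-phase proteins (2 of 4) and apoptosis regulators (9 of 15), 0.976 for leukocyte markers (0 of 1) and 0.99 for proliferation (10 of 20). Such counts moved with single lines: leaving out 1 line at a time, after the data were seen, gave 2 to 9 of 9 higher for interferon-stimulated genes, 1 to 8 of 11 for MHC class I antigen presentation and 1 to 9 of 10 for p53 target genes, and the counts of most other lists also changed. In the epithelial list the mean log2 fold change was 0.05 while the median (-0.02) and the test pointed lower, and in the protease list the median (0.19) and mean (0.02) lay above 0 while the test pointed lower.

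The count of 0 genes changed where wild-type line 2 was left out, which let 2 genes pass, Abhd16a and Wdr46, named after their values were seen, and where the 12 arrays were taken as independent, which called 156. Testing unnamed probes as well, an alternative chosen after seeing the data, let 1 probe pass.

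Lines of the same genotype were compared by an F test whose residual is the spread between arrays of a line, so its counts cannot be set against that of the genotype comparison. Among the wild-type lines 3393 of 7306 genes (46.4%) passed, and 1778 with median scaling. Of the 3393 genes, 721 had a range of line means over 1 log2 unit, and 4 of the 5 widest ranges came from genes undetected in line 1. They belonged to Acta2, Ly6e, BC018473, Igfbp4 and Lgals1. Acta2, the smooth muscle actin of myoepithelial cells and myofibroblasts, reached 13.94 ± 0.08 in line 2 (SD, n = 2 arrays) and was not detected in line 1, at least 212-fold lower (limma adjusted p = 3.17e-09). Ly6e, a membrane-anchored surface protein gene, and Igfbp4, encoding a binding protein of insulin-like growth factors, peaked in line 3 and were not detected in line 1, at least 194-fold and 52.2-fold lower. Lgals1, encoding galectin 1, was at least 89.7-fold lower in line 1 than in line 2. BC018473 ran the other way, at 11.65 ± 0.12 in line 1 and undetected in lines 2 and 3, at least 43.3-fold lower in line 3. These adjusted p-values rest on the spread between arrays of a line alone.

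The gene lists differed in how many members varied among wild-type lines. Whether a list held more or fewer passing members than other genes was tested with Fisher's exact test, a test chosen after seeing the data, in which genes are treated as independent though they are not. All 9 basal and myoepithelial markers differed (adjusted p = 0.00550). Krt14, a basal keratin, was at 7.51 in line 1 against 12.25 and 12.42 in lines 2 and 3, and Krt17, Mylk and Cav1 were not detected in line 1 while their means in the other wild-type lines lay between 8.24 and 11.15. All 9 interferon-stimulated genes differed (0.00550), with Gbp3 at 7.72, 9.47 and 10.78 and Oasl1 at 4.76, 6.55 and 7.46 in lines 1, 2 and 3. All 10 p53 target genes differed (0.00510), and the cell cycle inhibitor gene Cdkn1a stood at 12.04, 12.12 and 11.32. Of 10 cytokines and chemokines 9 differed (0.0341), among them Cxcl12, at 10.71 in line 2 against 7.18 and 7.69. Oxidative phosphorylation stood out in the other direction, with 1 of 33 genes differing (adjusted p = 8.50e-07). No other list passed this test.

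**Figure D3:**
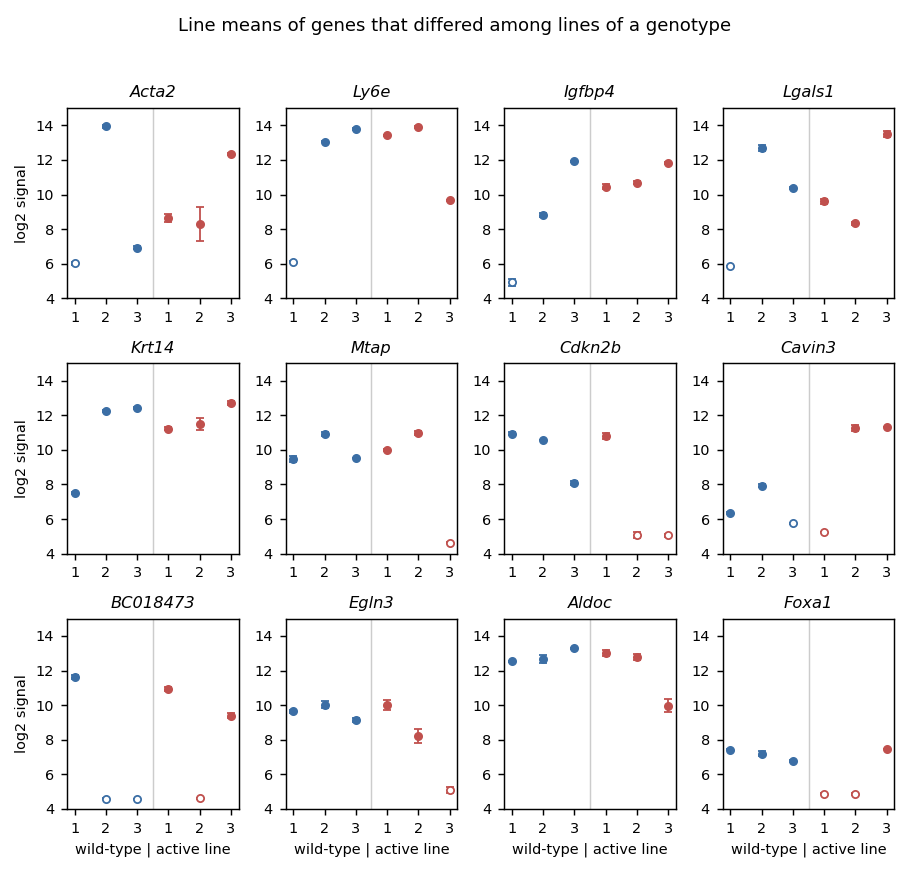
Log2 signal of 12 genes that differed among lines of a genotype, in the 3 wild-type (blue) and 3 constitutively active lines (red); points are means of 2 arrays, bars the SD of those arrays, and open points mark lines in which fewer than both arrays detected the plotted probe. Acta2, Ly6e, Igfbp4 and Lgals1 were undetected in wild-type line 1, and Mtap and Cdkn2b were undetected in constitutively active line 3.

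Among the constitutively active lines 4447 genes (60.9%) passed the F test, 962 with a range over 1 log2 unit, and 2746 passed with median scaling. Across genes line 3 stood apart, correlating at 0.939 and 0.943 with lines 1 and 2, which correlated at 0.973 with each other. The widest ranges belonged to Mtap, BC018473, Cavin3, Cdkn2b and Tns4. Mtap, an enzyme of methionine salvage, was at 10.97 ± 0.14 in line 2 and undetected in line 3, at least 26.1-fold lower (limma adjusted p = 5.70e-12). Cdkn2b, an inhibitor of cyclin-dependent kinases, was at 10.78 ± 0.18 in line 1 and undetected in lines 2 and 3, at least 22.9-fold lower in line 3. Cavin3, a protein of caveolae, was at 11.27 and 11.32 in lines 2 and 3 and undetected in line 1, at least 31.7-fold lower. BC018473 was at 10.93 ± 0.10 in line 1 and at least 28.0-fold lower in line 2. Tns4 was 51.9-fold higher in line 3 (12.45 ± 0.04) than in line 1 (6.75 ± 0.06).

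Constitutively active line 3 also carried less transcript of the receptor tyrosine kinase gene Kit, at 8.93 against 12.02 and 12.58 in lines 1 and 2, and of some feedback genes of the ERBB list, chosen after their values were seen: Spry4 was at 7.34 against 9.59 and 9.17, Etv5 at 10.03 against 11.75 and 12.20, and Dusp6 at 10.26 against 11.26 and 11.38. Others of that list ran differently: Dusp5 was highest in line 3, at 12.04 against 11.67 and 11.99 (limma adjusted p = 0.0316), and Egr1 did not pass (0.598). The hypoxia-responsive gene Egln3 was at 5.09 in line 3 against 10.01 and 8.23 by its brightest probe, while another of its probes was detected in line 3. Foxa1, a transcription factor of luminal cells, was undetected in lines 1 and 2 and at 7.47 in line 3. All of these but Egr1 passed the F test. Among the lists, oxidative phosphorylation again held few differing genes, 11 of 33 (33.3%; Fisher's exact adjusted p = 0.0414), and no other list passed that test; all 9 basal and myoepithelial markers and all 10 p53 target genes differed (adjusted p = 0.107 and 0.0917).

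**Figure D4:**
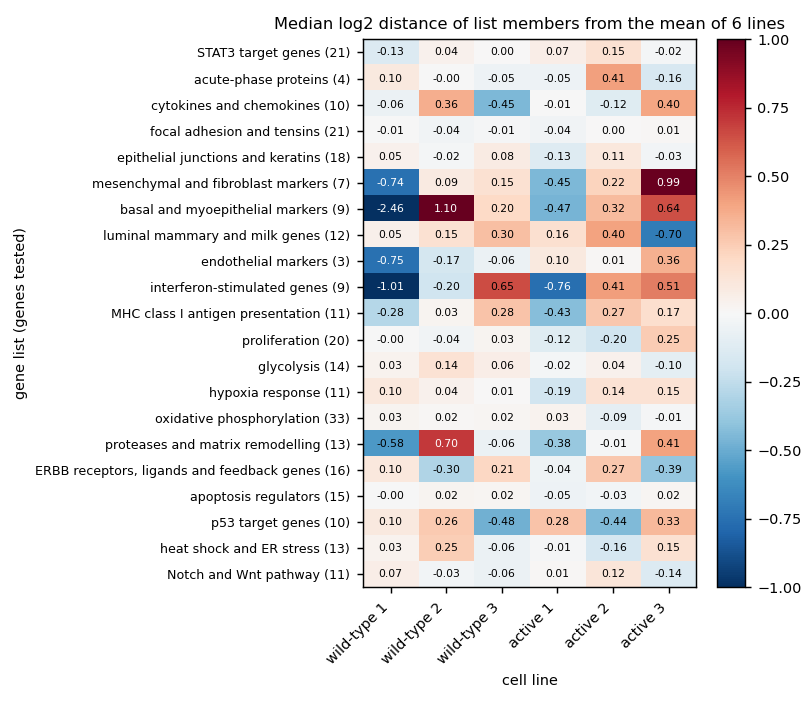
Median over the tested members of each gene list of the log2 distance between a line and the mean of the 6 lines, for the lists with more than 1 gene tested (number tested in parentheses); red is above and blue below the mean, and colours stop at -1 and 1. Basal and myoepithelial markers lie at -2.46 in wild-type line 1, and p53 target genes at -0.48 in wild-type line 3 and -0.44 in constitutively active line 2.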

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

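The test of all probes without regard to a gene name, the test on STAT3 target genes as an explanation and the other splits of the lines were chosen after the results were seen. A few keratin genes near Stat3 had also been seen before the test of its neighbours was set. A sample was called far from the rest when its gap to the nearest of the other arrays took more than Dixon's limit of the range of the 6 arrays of its genotype. Of 122 such groups 6 went over, and chance alone gives about 1 in 20 for independent values, which the 2 arrays of a line are not, so the chance rate here is not known. The gap took 0.685 of the range for the median raw signal of wild-type arrays, where replicate 2 of line 2 was the dimmest at 70.1. It took 0.693 for Slc4a11, 0.679 for Rnf145 and 0.644 for Sec61g in wild-type arrays, and 0.677 for Slc4a11 and 0.689 for Pxn in constitutively active arrays.

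Data outside the named genes held 1 probe whose signal went with the genotype. When all 11650 kept probes were tested, 1 unnamed probe (ILMN_2417233) passed with a limma adjusted p of 0.0441. It was undetected on all 6 wild-type arrays and detected on all 6 constitutively active arrays, at 9.60 ± 0.63 against 4.80 ± 0.07 (SD over lines), at least 11.1-fold higher. A probe of Cenpo had the reverse pattern, detected on all 6 wild-type arrays and on no constitutively active array. It did not pass (limma adjusted p = 0.843). Other splits of the lines were not run with unnamed probes, so how often they would let such a probe pass is not known. The gene of ILMN_2417233 is not named in the sources used here, and no biological explanation was tested for this probe alone.

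Tns4 and this probe share the pattern of background signal in the wild-type lines and detection in the constitutively active ones. A chromosomal segment around Stat3 that came with the altered allele could make neighbours of Stat3 differ by genotype more often than other genes. Of the 40 nearest tested genes 2 had lines that did not overlap between genotypes (5%), against 12.5% of the other genes (one-sided Fisher exact p = 0.967). Within this window of 20 tested genes on each side of Stat3, differences by genotype were thus no more frequent than elsewhere. A carried segment need not change the expression of its genes, and it may reach beyond this window. Tns4 is not among the 40, and its distance from Stat3 was not examined. The test therefore cannot exclude a carried segment, whether or not it holds Tns4. The position of the unnamed probe is not given in the sources used here. More transcription from STAT3 target genes stays possible but was not shown, since that list had a camera adjusted p of 0.759. The 6 lines leave open whether either signal follows the genotype, an array batch that went with it, or other differences between the tumours the lines came from.

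For the genotype comparison as a whole, 3 lines against 3 make 10 splits, too few for a share under 0.05. The genotypes gave 0 genes past the threshold and the highest of the other splits 1. At an unadjusted p under 0.05 the genotypes gave 410 genes and the highest other split 725. For lists, camera at its preset correlation passed 0 between genotypes and up to 10 in the other splits. With the correlation estimated from the data, run after that count was seen, 0 lists passed in any split, so those calls depend on the preset.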

How the results depend on the processing

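The test that includes unnamed probes was chosen after the data were seen; the other alternatives were planned. Between genotypes 0 genes passed with the deposited values, without background correction, with median scaling, without a filter, with detection on all arrays, with every named probe, with the line as a random block, with the trended and robust prior, at adjusted p under 0.1, with the fold threshold, and without any 1 array. Treating the 12 arrays as independent called 156 genes (56 higher, 100 lower), a count that takes repeats of a line for replicates. Including unnamed probes called 1 probe. Leaving out each line called 0 to 2 genes, the 2 without wild-type line 2 (Abhd16a and Wdr46). Neither replicate block changed the count of 0: it was 0 with array number as a block beside the random line term and 0 with cell line number as a block, and a block on array number gave 3292 genes among wild-type and 4376 among constitutively active lines. No list passed under any alternative run for lists, with smallest adjusted p-values from 0.0501 to 0.962. The random line block, with or without array number as a block, changed no list call. Cell line number as a block was not run for lists.

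Median scaling gave 1778 genes among the wild-type lines and 2746 among the constitutively active lines, against 3393 and 4447, and the cause was not tested. It moved the median log2 fold change of all genes from 0.01 to 0.21 and turned the split at unadjusted p under 0.05 from 148 higher and 262 lower to 831 higher and 52 lower, so directions of small changes hold only relative to the quantile-normalized distribution. Without arrays in turn the counts were 2578 to 3473 and 3979 to 4500. The unadjusted count of 410 ran from 188 without wild-type line 1 to 512 without constitutively active line 3, and was 1274 without a filter, 1410 with independent arrays, 262 with cell line number as a block and 654 with unnamed probes.

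Fold changes were followed through the alternatives for only part of the named genes. Among those, 9 values changed sign under an alternative, none of them past a threshold, and other named genes may change sign too. Zfp317 moved from -0.58 to 0.00622 among probes detected on all arrays. Leaving out 1 line at a time gave Krt14 from -0.53 to 1.93, Acta2 from -0.67 to 3.30, Ly6e from -1.10 to 2.75, Lgals1 from -1.05 to 2.38 and Mtap from -2.62 to 0.51. A further 25 of the fold changes followed passed the threshold with independent arrays alone. A slide could not be used as a block because none is given, and dim probes are limited by signal over background, with 23.6% to 27.4% of probes detected per array.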

Other observations

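The test on probes as bright as Mtap, the test of genes on the chromosome of Abhd16a, the values of single arrays and the genes named here were chosen after values were seen. The test on probes as bright as Mtap was added when the share of lost probes fell between the bounds set for it. The other tests were set before their results were seen, on patterns found in the same data.

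Interferon-stimulated genes and MHC class I genes had their lowest medians in wild-type line 1 and constitutively active line 1. The medians of the interferon list, as log2 distances from the mean of the 6 lines, were -1.01 and -0.76 there, against -0.20 to 0.65 in the other lines. In constitutively active line 2 the arrays disagreed, at -0.23 and 1.16, so the level of that line depends on the array. The line medians of the MHC class I list were -0.28 and -0.43, against 0.03 to 0.28.

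Mtap and Cdkn2b, neighbours on their chromosome, were both undetected in constitutively active line 3. A sequence variant under a single probe is argued against by 4 separate probes of Mtap, Cdkn2a and Cdkn2b that were lost there. Low signal on the arrays is argued against by 1459 other probes as bright as Mtap in raw signal and detected on all other arrays, of which 1 was undetected there (0.0685%), although 120 of all 8394 probes detected on all other arrays (1.43%) were lost. Of the 3 probes of Cdkn2a, which lies between them, 0 were detected on both arrays, but 1 was detected in no line and another was also undetected in wild-type line 3 and constitutively active line 2, so the test rests on 2 probes, and loss of the segment is a candidate explanation, untested on DNA. Silencing of the genes stays open, and Cdkn2b was also undetected in constitutively active line 2, where Mtap was detected.

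The p53 target genes had their lowest medians in wild-type line 3 and constitutively active line 2, at -0.48 and -0.44. A hypothesis is that p53 activity may be lower in those lines. In a second list of 18 p53 target genes, written before its values were seen, the same lines had the lowest medians, -0.20 and -0.22, and the higher of their percentiles among 10000 random lists matched to it was 0.06. Random lists ignore that p53 targets vary together, and these lines are also the most alike of the 6 (r = 0.982 across genes). Technical explanations were not weighed for this pattern.

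Abhd16a was undetected in wild-type lines 1 and 3 (5.09 and 5.17) and bright in the other 4 lines (9.80 to 10.01), which is why it passed between genotypes when wild-type line 2 was left out. A haplotype that differs between lines may be the source: Wdr46, Zbtb22 and Vps52, on the same chromosome, were also dimmer in wild-type lines 1 and 3 (Wdr46 5.42 and 5.17 against 7.78 to 8.24, Zbtb22 9.38 and 9.33 against 10.70 to 10.86, Vps52 5.78 and 5.63 against 7.14 to 7.64), though they were picked because they show it, and Nenf, on another chromosome, had the same split (8.84 and 8.62 against 11.64 to 12.23). At an absolute r with Abhd16a over 0.9, however, 1 of its 40 nearest tested genes, Clic1, moved with it, in the opposite direction (2.5% against 1.27% of other genes, one-sided Fisher exact p = 0.402). Those 40 genes do not include Wdr46, Zbtb22 or Vps52, so that test could not count them. Of the 93 genes at such an r, 7 lay on its chromosome, of which Clic1 and Rsph3a ran opposite (7.53% against 5.02%, one-sided Fisher exact p = 0.190). That test counts a whole chromosome and does not ask whether these genes lie close together, so a haplotype stays open. A variant or deletion affecting its probe alone stays open too, since 0 other probes of the gene were on hand to compare. No biological explanation was tested.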
